A study of Mus musculus with 4 samples.

How the data were processed

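RNA was measured on 4 single-channel Affymetrix arrays, 2 from control RNAi cells and 2 from Npac RNAi cells, with the groups and replicate numbers taken from the sample titles. Per the labels' protocols, mouse E14 embryonic stem cells were grown in medium with 15% serum and 1000 units per ml of LIF, transfected with a short hairpin RNA, placed under puromycin 24 hours later and harvested after 3 days of selection. Biotin-labelled complementary RNA was then made from 5 µg of total RNA. The hairpin used in the control cells is not described in the sources used here.

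The deposited values are on a log2 scale, 1 value per probe set and array, and RMA (robust multi-array averaging, which corrects background, equalises the probe signals between arrays and summarises them per probe set) is named in the submitters' processing notes without a version. No log base was stated in the deposited value table. A log2 scale was inferred from the values, which, control probe sets aside, ran from 2.78 to 15.05 with array medians between 6.41 and 6.44. Software, probe set definitions and any further scaling are not given in the sources used here. Because RMA equalises arrays, a change shared by most transcripts would be removed from the values before any test, so differences are relative to the bulk of the transcripts on the array.

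Of 45101 probe sets, 64 were manufacturer's controls and were kept out of the gene tests, 34945 carried 1 gene symbol, 932 carried several and 9160 were not named in the annotation used here. No gene was named from a probe set with several symbols. Symbols were updated through Entrez identifiers against RefSeq genes of the assembly GRCm38.p6, which was used for names only. This matched 34741 probe sets, and the other 204 kept the symbol of the array annotation. Each gene was represented by its probe set with the highest mean over the 4 arrays, a choice that uses no group information. This left 18193 genes. No filter on dim probe sets was applied.

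The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust fitting, group as the only term) and p-values were adjusted with the Benjamini-Hochberg method over the 18193 genes. A gene was called at an adjusted p under 0.05, and standard errors (SE) are limma's moderated ones. The fit had 2 residual degrees of freedom, and the prior added 2.28. For 136 genes both replicates of a group had identical values. On simulated data built from these arrays with 200 changed genes, the procedure called 11.9% of genes changed by 0.5, 88.1% of those changed by 1 and 95.5% of those changed by 2 on the log2 scale, along with 5 unchanged genes. With as many changed genes as were called in the real comparison, each given its observed difference, 76.8% were recovered and 2.63% of the calls fell on unchanged genes. Both simulations drew noise independently for each gene, with variances from limma's fitted prior. They hold no effect shared by the genes of an array, so these rates are not error rates of the real calls.

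A set of 31 gene lists was fixed before the data were examined, covering pluripotency states, embryonic lineages, cell cycle, p53 and stress responses, signalling, chromatin, imprinting, metabolism and feeder fibroblasts. Of their 799 entries 713 were measured. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 31 lists. Camera with an estimated correlation, fry and a count of members adjusted over the list alone were also run. The estimated form rests on the 2 residual degrees of freedom of the fit, so few lists can pass it. A call lost there cannot tell correlation among genes from that lack of power. Lists share some genes, for example Krt18 between trophectoderm and primed pluripotency and Ascl2 between trophectoderm and imprinted genes.

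Genes were named by a rule set before the data were examined. It takes Glyr1, then the 10 most raised and the 10 most lowered called genes that had groups without overlap and a mean at or above the median of all genes (7.49), skipping predicted genes. It adds up to 2 higher and 2 lower called members of each list with the smallest adjusted p, and always Pou5f1, Nanog, Sox2, Klf4 and Esrrb. Some of the list members so selected, such as Hoxd1, Hoxb3, Col3a1 and Mgp, all lower, are not described below. A gene named outside the rule is said to have been chosen after its values were seen.

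Alternatives were other forms of the empirical Bayes step, quantile, median and cyclic loess normalization of the deposited values, filters on dim genes, other choices of probe set, a stricter threshold, a minimum fold, the replicate number as a block, and each array left out in turn. Leaving out 1 array leaves a lone array in its group, which is then assumed to vary like the other group. Scaling on the poly-A spike-ins, bacterial transcripts added to the RNA before labelling, was added after their values were seen, as were a crossed replicate block and the gene list tests after cyclic loess and spike-in scaling. A bootstrap of the trophectoderm median (10000 draws) was computed in Python 3.11.15 with numpy 2.4.6. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision.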

Results

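Expression was profiled in E14 cells, a mouse embryonic stem cell line kept undifferentiated by LIF, after RNA interference against Npac or with a control. Npac is the older name of Glyr1, a chromatin protein that binds nucleosomes through a domain recognising methylated H3K36, a histone mark of transcribed gene bodies. The data were 4 arrays, 2 per group, harvested after 3 days of puromycin selection. Replicate arrays correlated at 0.998 in each group and arrays of different groups at 0.987 to 0.989 (Pearson's r across probe sets other than controls, which are not independent replicates).

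The comparison asked which transcripts differed when Npac was depleted. The targeted gene was read first. Glyr1 stood at 10.23 and 10.20 on the Npac RNAi arrays and at 11.30 and 11.32 on the control arrays, a log2 difference of -1.09 (SE 0.0458, limma adjusted p = 0.00101, n = 2 arrays per group) that left 46.9% of the control level. It was measured by 1 probe set. Without any 1 array the difference stayed between -1.10 and -1.08.

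Npac depletion was accompanied by higher levels of trophectoderm genes, such as the placental transcription factor gene Ascl2 (6.44-fold), and of p53 targets, such as the cell cycle inhibitor Cdkn1a (3.22-fold). Genes of pluripotency and of the cell cycle were lower, among them the pluripotency factor Pou5f1 (2.25-fold) and the DNA topoisomerase Top2a (1.59-fold). These list shifts passed camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.366 for each), which has little power at 2 residual degrees of freedom. The median of the p53 targets fell from 0.57 to 0.03 with spike-in scaling. The maternally silenced growth factor gene Igf2 rose 6.57-fold, and Rian, a noncoding RNA of the imprinted Dlk1 and Meg3 locus, fell 5.86-fold. The log2 difference of Rian was -2.55 on the deposited values and ran from -3.09 to -1.73 over 20 settings. In total 7425 of 18193 genes (40.8%) passed the limma test, 4020 higher and 3405 lower in Npac RNAi. Changes of at least 1.5-fold were found for 1842 genes, 1471 higher and 371 lower, and of at least 2-fold for 578, of which 531 were higher and 47 lower.

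Leaving out any 1 array lowers the residual degrees of freedom and with them the power. A call lost in this way need not mean that a gene depends on that array. The number of calls changed with the arrays used and with the scaling. It was 4108 without control array 1, 3088 without control array 2, 4731 without Npac array 1 and 3440 without Npac array 2, and 2551 with no empirical Bayes moderation. The share of calls that were higher was 54.1% as deposited, 44.1% after a further quantile normalization and 28.4% after centring on the median of all genes, which shifted every log2 difference by -0.14. Centring made the array medians equal, but it moved the median log2 difference over genes from -0.04 to -0.18. It thus took the typical gene further from no difference. The 24 poly-A spike-in probe sets read 0.54 higher on the Npac RNAi arrays, in 24 of 24 probe sets. They are repeated readings of the transcripts dap, lys, phe and thr, not independent ones. Scaling on these probe sets shifted every log2 difference by -0.54 and left 906 genes higher and 14895 lower (5.73% higher). The 2-fold calls, 531 higher and 47 lower as deposited, were 382 and 105 after centring, 357 and 41 with the mean of probe sets and 169 and 853 with spike-in scaling. The 1.5-fold calls, 1471 higher and 371 lower as deposited, were 1202 and 602 after quantile normalization, 1025 and 945 after centring and 397 and 8994 with spike-in scaling. Directions below are relative to the bulk of transcripts, and a rise smaller than 0.54 changes sign under the spike-in scaling, while one slightly larger shrinks toward 0. Counts of lower genes after centring and spike-in scaling hold these constant shifts, which can also make unchanged dim genes lower. Without moderation the calls on the named genes Nanog, Neurod1, Sox11, Amn, Bst2, Nelfa, Hoxb13, Zeb1, Acvr2b, Rpl14, Klf4, Zfp281 and Cdc25b were lost. So were those on Cdx2, Tfap2c, Cdh1, Grhl2, Cldn6, Acta2, Snai1, Snai2, Meg3, Igf2r, Zfp352, Tdpoz1 and Usp17la, which were named after their values were seen.

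The 10 most raised genes under the naming rule lay between 2.57 and 2.94 on the log2 scale, each with an adjusted p of 0.000704. They were the homeobox genes Rhox6 (2.94, SE 0.0455) and Rhox9 (2.59, SE 0.0457), the peripheral myelin gene Pmp22 (2.94, SE 0.0685), the macrophage growth factor Csf1 (2.91, SE 0.0912) and the chemokine Cxcl10 (2.90, SE 0.0516). The others were Igf2 (2.72, SE 0.0476), the transcriptional cofactor Vgll3 (2.71, SE 0.073), Ascl2 (2.69, SE 0.0551), the ferritin-like gene Fthl17a (2.64, SE 0.0838) and the Wnt antagonist Dkk1 (2.57, SE 0.07). The 10 most lowered ran from Rian (-2.55, SE 0.0873) through the neuronal stathmin Stmn2 (-2.03, SE 0.0498) and Tcl1, an activator of Akt signalling in embryonic stem cells (-1.90, SE 0.0541), to Lrrc2 (-1.43, SE 0.0778). Between them lay Pramel7 (-1.68, SE 0.0545), Pramel6 (-1.67, SE 0.0741), the snoRNA host gene Snhg3 (-1.52, SE 0.077), Trim43a (-1.46, SE 0.0588), the nuclear receptor Nr0b1 (-1.43, SE 0.0451) and the hormone gene Trh (-1.43, SE 0.0531). Rhox6, Rhox9, Fthl17a, Pramel6, Pramel7 and Trim43a belong to multigene families, so probes may also bind transcripts of close relatives, and their values are uncertain in that respect. Csf1 rose by 1.22 when all its probe sets were averaged.

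**Figure D1:**
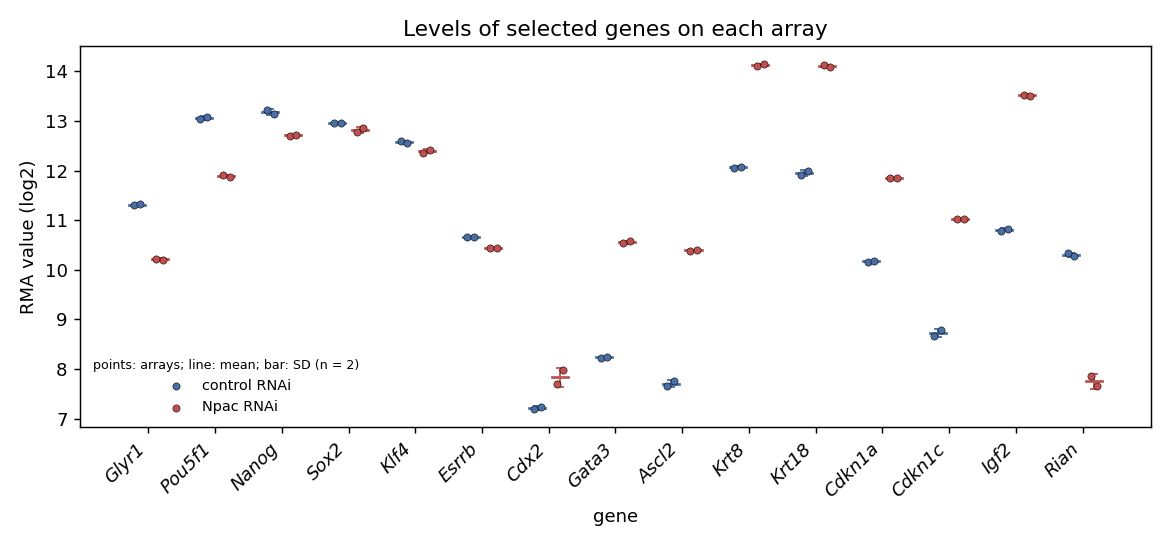
RMA values (log2, vertical axis) of 15 genes on each array, with points for arrays, a line for the group mean and a bar for the SD (n = 2 arrays per group). Glyr1, Pou5f1 and Rian were lower and Ascl2, Krt18, Cdkn1a, Cdkn1c and Igf2 higher in Npac RNAi as deposited and after quantile, median, cyclic loess and spike-in scaling, whereas the gap of Sox2 (-0.14) did not pass the test on the deposited values.

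Genes of general pluripotency fell together. Of 19 measured, 14 were lower and 1 higher, and the counts were also 14 and 1 when adjusted over the list alone (median log2 difference -0.36, camera adjusted p = 4.19e-05, but adjusted p = 0.366 with an estimated correlation). Pou5f1, the Oct4 gene, fell from 13.06 ± 0.036 to 11.89 ± 0.0195 (mean ± SD, n = 2; log2 difference -1.17, SE 0.0491, limma adjusted p = 0.00101), and Tdgf1, a Nodal co-receptor gene, fell by 1.23 on the log2 scale (SE 0.0457). Nanog fell less (-0.48, SE 0.0527, limma adjusted p = 0.00562). Sox2 did not pass the test on the deposited values (-0.14, SE 0.0541, limma adjusted p = 0.105), but was called lower after centring (-0.28), with spike-in scaling (-0.68), with the trend option and among genes at or above the median level. The member that rose was the zinc finger gene Zfp281 (0.20, SE 0.0475), which was lower under spike-in scaling (-0.34). With 1 array left out, 9 to 11 members were lower, fewest without control array 2.

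Naive pluripotency genes, which mark the ground state of embryonic stem cells, were also lower. Of 24 measured, 18 fell and 2 rose (18 and 3 adjusted over the list alone; median -0.39, camera adjusted p = 0.000261, adjusted p = 0.366 with an estimated correlation). Tcl1 and Nr0b1 fell most clearly, and Klf4 (-0.19, SE 0.0508, limma adjusted p = 0.0474) and Esrrb (-0.22, SE 0.0452, limma adjusted p = 0.0226) fell slightly. The calls on Klf4, Esrrb and Zfp281 were lost without any 1 of the 4 arrays, at adjusted p up to 0.172, 0.0989 and 0.135. Over 20 settings their adjusted p ran from 0.000207, 0.000197 and 0.000749 to 1. The members that rose were Dppa3 (0.65, SE 0.0556), a maternal factor that protects DNA methylation, and the T-box gene Tbx3 (0.39, SE 0.0476). With spike-in scaling the call on Dppa3 was lost (0.11) and Tbx3 turned (-0.15), and Tbx3 was 0.23 with the mean of probe sets. Formative and primed pluripotency genes did not shift as a list (19 measured, 3 higher and 6 lower, the same counts adjusted over the list alone, camera adjusted p = 0.449). Among them the keratin gene Krt18 (2.15, SE 0.0543) and Sox4 (0.74, SE 0.0493) rose, and the transcription factor genes Tcf15 (-0.98, SE 0.0492) and Sox3 (-0.64, SE 0.0449) fell. Sox3 had identical values on both control arrays, so its SE rests almost wholly on limma's prior. Its mean level of 6.57 lay below the median of all genes (7.49). Averaging probe sets gave 0.25 for Sox4 and -0.40 for Sox3, and Sox4 lost its call with spike-in scaling (0.20). The list gave 3 higher and 10 lower after centring and 1 and 15 with spike-in scaling.

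Markers of trophectoderm, the outer layer of the blastocyst that forms the placenta, rose most of the 31 lists by median. Of 22 measured, 18 were higher and 0 lower (19 and 2 adjusted over the list alone), and the median difference was 1.55, or 2.92-fold (camera adjusted p = 1.23e-09, adjusted p = 0.366 with an estimated correlation). With spike-in scaling the median was 1.01, with 16 higher and 3 lower. Besides Rhox6, Rhox9 and Ascl2, members chosen after their values were seen were the lineage regulator Gata3 (2.32, SE 0.0474), the keratins Krt7 (2.52, SE 0.0851) and Krt8 (2.06, SE 0.0476), Tfap2c (1.84, SE 0.127) and Cdx2 (0.63, SE 0.104). The call on Cdx2 was lost without either control array (adjusted p up to 0.0759, range over 20 settings 0.000834 to 0.45) and with spike-in scaling (0.09), and its value was 0.41 with the mean of probe sets. The 4 members without a call, named after their values were seen, were Elf5 (0.42, SE 0.151), Esx1 (0.04, SE 0.111), Psg17 (-0.16, SE 0.0512) and Tpbpa (-0.25, SE 0.0799), the last being a marker of the ectoplacental cone and spongiotrophoblast. Elf5 depended on the probe set and was called lower for the one with the largest interquartile range (-0.41, limma adjusted p = 0.0121). Tpbpa and Psg17 were called lower after centring (-0.39 and -0.30), and Elf5 and Esx1 were below 0 with spike-in scaling (-0.12 and -0.50). Elf5, Psg17 and Tpbpa were dim, below the 25th percentile of all genes (5.51), with Psg17 at 3.94 in control RNAi. Whether these genes changed is uncertain at such levels.

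The markers of other cell types did not move in this way. Two-cell-like state genes, a signature of rare cells resembling the early embryo, fell as a list, although only 8 of the 23 listed were measured. Of these 5 were lower and 0 higher (6 and 0 adjusted over the list alone, median -0.28, camera adjusted p = 0.0226, adjusted p = 0.375 with an estimated correlation). Sp110 (-0.86, SE 0.0531) and Tcstv3 (-0.51, SE 0.0459), a multigene family member, led. The other called members, named after their values were seen, were Zfp352 (-0.46), Tdpoz1 (-0.27) and Usp17la (-0.21). The calls on Tdpoz1 and Usp17la were lost without any 1 of the 4 arrays (adjusted p up to 0.102 and 0.147, highest over all settings 1) and that on Zfp352 without Npac array 2 (0.051, range over 20 settings 2.94e-05 to 0.105). Sp110 was -0.45 with the mean of probe sets. Centring gave 7 lower and spike-in scaling 8. With 1 array left out 2 or 3 members were lower, and the list's call was lost with spike-in scaling (camera adjusted p = 0.0859, against 0.00735 to 0.0418 in the other 11 settings of the preset camera test). Among 20 neuroectoderm genes 2 were higher and 7 lower (2 and 9 adjusted over the list alone, camera adjusted p = 0.199), with the proneural gene Neurod1 up (1.75, SE 0.117) and Sox11 down (-0.52, SE 0.0567; -0.27 with the mean of probe sets), and 1 higher and 17 lower with spike-in scaling. Among 23 genes of primitive streak and mesoderm 6 rose and 6 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.933). The risen ones included Gata2 (2.27, SE 0.0539) and Eomes (1.24, SE 0.0689), which also act in trophoblast. Of 25 endoderm genes 9 rose and 6 fell (11 and 6 adjusted over the list alone, camera adjusted p = 0.292), with the basement membrane collagens Col4a2 (2.30-fold) and Col4a1 (0.98, SE 0.0492) higher and Amn (-0.74, SE 0.0893) lower. Of 21 germline genes 9 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.187), led by Taf7l (1.41, SE 0.0543). The balance turned with the scaling: germline genes gave 7 higher and 9 lower after centring and 2 and 14 with spike-in scaling, mesoderm genes 4 and 10 and 2 and 17, and endoderm genes 8 and 9 and 5 and 16. The endoderm list passed camera with spike-in scaling (adjusted p = 0.039, range over 12 settings 0.039 to 0.604), as higher than the other genes, although its median was then -0.52. When 1 array was omitted, the neuroectoderm genes lower numbered 2 to 5, the mesoderm genes 3 or 4 higher and 0 to 2 lower, the endoderm genes 5 to 9 higher and 3 to 5 lower, and the germline genes 5 to 7 higher and 0 or 1 lower.

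Fibroblast markers, listed because feeder cells can be present in stem cell cultures, gave 7 higher and 2 lower of 21 (the same counts adjusted over the list alone, camera adjusted p = 0.151). The actin-binding gene Tagln (2.38, SE 0.0639) and Col5a1 (1.18, SE 0.0691; 0.71 with the mean of probe sets) rose. The abundant fibroblast collagens Col1a1 (-0.05, SE 0.0583) and Col1a2 (0.11, SE 0.0862), named after their values were seen, had no call on the deposited values and differed in sign between settings. With 1 array left out 4 to 7 were higher and 0 lower, and the list passed the test in 5 of 12 settings (camera adjusted p from 0.00779 to 0.184). These were without Npac array 2 (0.0353), after quantile normalization (0.012) and cyclic loess (0.0178), with spike-in scaling (0.00779) and among genes at or above the median level (0.0485). In the last the 5 members kept had a median of 1.18, against 0.06 for all 21. Spike-in scaling gave 4 higher and 13 lower, with a median of -0.48.

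Targets of p53, the transcription factor activated by DNA damage and other stress, rose as a list. Of 24 measured, 18 were higher and 0 lower (18 and 1 adjusted over the list alone), with a median of 0.57, or 1.48-fold (camera adjusted p = 3.47e-07, adjusted p = 0.366 with an estimated correlation), and a median of 0.03 with spike-in scaling. The counts were 17 higher and 3 lower after centring and 9 and 7 with spike-in scaling. Perp, a desmosome and apoptosis gene, rose 5.48-fold (2.45, SE 0.0621), and Cdkn1a rose from 10.17 ± 0.0163 to 11.85 ± 0.00455 (mean ± SD, n = 2). Mdm2 (1.18, SE 0.0465) and Fas (1.42, SE 0.0916), chosen after their values were seen, rose too. Apoptosis regulators gave 12 higher and 4 lower of 22 (12 and 5 adjusted over the list alone, camera adjusted p = 0.0674). The risen ones included Birc3, an inhibitor of apoptosis gene (0.998, SE 0.0549), and the BH3-only gene Bik (0.85, SE 0.0571). Genes for and against apoptosis are mixed in this list, so its counts give no direction for that process. That list passed the test without Npac array 2 (camera adjusted p = 0.0471, range over 12 settings 0.0066 to 0.312), after centring (0.0144) and with spike-in scaling (0.0066), where 4 were higher and 11 lower, and 0 or 1 of its members were lower with 1 array left out.

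Genes of the cell cycle fell by smaller steps. Of 26 S phase genes 22 were lower and 0 higher (22 and 1 adjusted over the list alone, median -0.42, camera adjusted p = 5.29e-07, adjusted p = 0.366 with an estimated correlation). Among them were the replication factors Gins2 (-0.64, SE 0.0488) and Mcm10 (-0.63, SE 0.046). Of 27 genes of G2 and M phase 21 were lower and 1 higher (22 and 1 adjusted over the list alone, median -0.34, camera adjusted p = 1.83e-06, adjusted p = 0.366 with an estimated correlation). They included Top2a (-0.67, SE 0.0462) and the mitotic kinase Aurka (-0.67, SE 0.0529). The member that rose was the phosphatase Cdc25b (0.20, SE 0.0499), which was lower under spike-in scaling (-0.34) and lost its call without any 1 of the 4 arrays (adjusted p up to 0.142, range over 20 settings 0.00647 to 1). Without any 1 array 13 to 16 S phase genes and 12 or 13 genes of G2 and M phase were lower.

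Genes responding to TGF-beta, Nodal and BMP signalling were higher as a list, with 10 higher and 2 lower of 18 (the same adjusted over the list alone), a median of 0.34 as deposited and -0.20 with spike-in scaling (camera adjusted p = 0.0216, adjusted p = 0.436 with an estimated correlation). Spike-in scaling turned the counts to 4 higher and 9 lower. Cdkn1c, an imprinted cell cycle inhibitor (2.30, SE 0.0611), and the matrix protein Ccn1 (1.78, SE 0.0661) rose. The activin subunit gene Inhbb fell (-0.95, SE 0.0487), as did the receptor gene Acvr2b (-0.28, SE 0.054), whose call was lost without any 1 of the 4 arrays (adjusted p up to 0.0883, range over 20 settings 0.000148 to 1). The list's call was lost after cyclic loess (camera adjusted p = 0.051) and among genes at or above the median level (0.202; range over 12 settings 9.24e-05 to 0.202).

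Genes of the epithelial to mesenchymal transition list were higher on balance, with epithelial genes among them. Of 20 measured, 9 were higher and 3 lower (9 and 3 adjusted over the list alone), with a median of 0.22 as deposited and -0.32 with spike-in scaling (camera adjusted p = 0.047, adjusted p = 0.383 with an estimated correlation). The counts were 9 higher and 6 lower after centring and turned to 5 and 10 with spike-in scaling. The tight junction gene Cldn4 (2.36, SE 0.0508) and the epithelial splicing regulator Esrp1 (1.07, SE 0.047) rose. So did the epithelial genes Cldn6 (1.10), Cdh1 (0.67), Grhl2 (0.61) and Epcam (0.48), chosen after their values were seen, but Epcam was -0.06 with spike-in scaling, where the calls on Cdh1 (0.13) and Grhl2 (0.07) were lost. With the mean of probe sets Grhl2 lost its call (0.03) and Epcam was 0.24. The mesenchymal members Acta2 (1.23), Mmp9 (0.85) and Snai1 (0.42), also chosen after their values were seen, rose as well. Acta2 was 0.36 with the mean of probe sets, and Snai1 was -0.12 with spike-in scaling and lost its call without control array 2 and without either Npac array (adjusted p up to 0.0694, range over 19 settings 0.00955 to 0.265). The 3 that fell were fibronectin, Fn1 (-0.40, SE 0.0463), and the mesenchymal transcription factor genes Zeb1 (-0.38, SE 0.0592) and Snai2 (-0.32, SE 0.0763), the last named after its value was seen. Snai2 lost its call without either control array and without Npac array 1 (adjusted p up to 0.133, range over 20 settings 0.00013 to 0.806), and Zeb1 was -0.79 for the probe set with the largest interquartile range. Omission of 1 array left 8 to 10 higher and 1 or 2 lower, and Zeb1 lost its call without either control array and without Npac array 2 (adjusted p up to 0.074, range over 20 settings 0.000174 to 0.299). The list's call was lost without control array 2 (camera adjusted p = 0.0588), without Npac array 1 (0.051), after cyclic loess (0.051) and among genes at or above the median level (0.412; range over 12 settings 0.00069 to 0.412).

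Other response lists held members moving both ways and did not pass the camera test on the deposited values. FGF and ERK response genes split, with 11 higher and 6 lower of 24 (11 and 7 adjusted over the list alone, camera adjusted p = 0.187). Klf6 (1.54, SE 0.0454) and the phosphatase Dusp1 (1.32, SE 0.045) rose, and the feedback inhibitor Spry4 (-0.95, SE 0.0551) and Ier2 (-0.78, SE 0.0504) fell. The FGF and ERK list passed camera after centring (adjusted p = 0.0256) and with spike-in scaling (1.64e-05, range over 12 settings 1.64e-05 to 0.982), as higher than the other genes, although spike-in scaling gave 8 higher and 12 lower. Wnt response genes gave 3 higher and 6 lower of 18 (3 and 6 adjusted over the list alone, camera adjusted p = 0.715), with Dkk1 up and Sfrp1 (-1.38, SE 0.0707) and Fzd5 (-0.92, SE 0.0662) down. Of 22 interferon response genes Cxcl10 rose and 6 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.36), Bst2 among them (-0.56, SE 0.0667). The integrated stress response list gave 7 higher and 12 lower of 25 (7 and 12 adjusted over the list alone, camera adjusted p = 0.337). Cebpb rose (1.74, SE 0.0499) and the serine synthesis gene Psat1 fell (-0.85, SE 0.0472). Heat shock genes gave 4 higher and 5 lower of 14 (5 and 7 adjusted over the list alone, camera adjusted p = 0.933), with Hmox1 up (1.35, SE 0.0468) and Hsph1 down (-0.69, SE 0.0453). On leaving out 1 array, the lower members numbered 3 to 5 for FGF and ERK, 2 to 4 for Wnt (1 to 4 higher), 1 to 3 for interferon, 8 to 10 for integrated stress and 1 or 2 for heat shock. With spike-in scaling the counts were 1 higher and 14 lower for Wnt, 1 and 20 for interferon, 3 and 19 for integrated stress and 3 and 10 for heat shock, and after centring the lower ones were 9, 11, 15 and 8.

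Imprinted genes, expressed from 1 parental copy, held some of the largest changes in both directions. Of 26 measured, 13 were higher and 5 lower (13 and 6 adjusted over the list alone, camera adjusted p = 0.0674). Igf2, Ascl2 and Cdkn1c rose, as did Phlda2 (1.93, SE 0.0563) and Peg3 (1.76, SE 0.0464), chosen after their values were seen. The 5 that fell were Rian, the zinc finger gene Plagl1 (-1.10, SE 0.0694) and, named after their values were seen, Mirg (-0.84, SE 0.0568), Meg3 (-0.74, SE 0.0639) and Igf2r (-0.45, SE 0.0561). Rian, Mirg and Meg3 are noncoding RNAs of 1 locus. The mean of probe sets gave 0.95 for Peg3, -0.66 for Plagl1 and -0.21 for Igf2r. The list passed the test without Npac array 1 (camera adjusted p = 0.0473, range over 12 settings 2.07e-05 to 0.294), after centring (0.0127), with the mean of probe sets (0.0164) and with spike-in scaling (2.07e-05), where 9 were higher and 15 lower.

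Chromatin lists did not pass the camera test on the deposited values. Genes of transcription elongation and H3K36 methylation, the processes closest to the known binding of Npac, gave 14 higher and 7 lower of 37 (14 and 8 adjusted over the list alone, camera adjusted p = 0.294). The Paf1 complex gene Ctr9 (0.76, SE 0.0488) and the elongation factor gene Ell (0.67, SE 0.0537) rose, and the NELF subunit genes Nelfcd (-0.46, SE 0.0452) and Nelfa (-0.43, SE 0.0518) fell. Ell was 0.35 with the mean of probe sets and lost its call with spike-in scaling (0.13). This balance turned with the scaling, to 10 higher and 10 lower after quantile normalization, 10 and 17 after centring and 1 and 27 with spike-in scaling. Polycomb genes gave 11 higher and 5 lower of 26 (12 and 7 adjusted over the list alone, camera adjusted p = 0.187), with Pcgf5 up (1.03, SE 0.0486) and Phc1 down (-0.70, SE 0.0458), but 6 higher and 9 lower after centring and 2 and 20 with spike-in scaling. DNA methylation genes gave 4 higher and 9 lower of 16 (4 and 10 adjusted over the list alone, median -0.37, camera adjusted p = 0.134). The dioxygenase gene Tet1 (-0.79, SE 0.0559) and the methyltransferase gene Dnmt3a (-0.56, SE 0.0458) fell, and Mbd2 rose (0.64, SE 0.0504). The call on Dnmt3a was lost with the mean of its probe sets (-0.05, adjusted p = 0.533, range over 20 settings 1.2e-05 to 0.533) and that on Mbd2 with spike-in scaling (0.10), which gave 0 higher and 12 lower in the list. That list passed camera, as lower, among genes at or above the median level (adjusted p = 0.0485) and after cyclic loess (0.0468, range over 12 settings 0.0468 to 0.376). Hox genes gave 4 higher and 6 lower of 33 (3 and 2 adjusted over the list alone, camera adjusted p = 0.703), the risen ones including Hoxb13 (1.13, SE 0.11) and Hoxc13 (0.85, SE 0.0609). Hox genes gave 4 higher and 2 lower after cyclic loess, 3 and 13 after centring and 2 and 28 with spike-in scaling. Omitting 1 array, 5 to 9 elongation genes were higher and 3 or 4 lower, 5 or 6 Polycomb genes higher and 1 to 3 lower, 6 or 7 methylation genes lower, and 3 Hox genes higher and 0 or 1 lower.

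Cholesterol synthesis genes fell, with 7 lower and 0 higher of 17 (11 and 1 adjusted over the list alone, median -0.20, camera adjusted p = 0.0079, adjusted p = 0.42 with an estimated correlation). Insig1, a sterol-regulated target gene (-1.10, SE 0.0684), and the isomerase Idi1 (-0.70, SE 0.0475) led. Without control array 2 the number lower was 3, and it was 6 or 7 without any other array, 13 after quantile normalization or centring and 17 with spike-in scaling. Ribosome biogenesis genes gave 14 lower and 2 higher of 30 (the same adjusted over the list alone, median -0.16, camera adjusted p = 0.0235, adjusted p = 0.371 with an estimated correlation). Rrp1b (-0.68, SE 0.0561) and the helicase Ddx18 (-0.48, SE 0.0464) fell (-0.45 and -0.31 with the mean of probe sets). Spike-in scaling gave 29 lower and 0 higher. The members that rose, Utp20 (0.34, SE 0.0463) and Utp4 (0.26, SE 0.047), were lower under spike-in scaling (-0.20 and -0.28). Utp20 lost its call without control array 2 and without Npac array 2 (adjusted p up to 0.0566, range over 20 settings 1.46e-05 to 0.365) and Utp4 without any 1 of the 4 arrays (up to 0.0828, range 6.85e-05 to 1). The list's call was lost without Npac array 1 (camera adjusted p = 0.0525, range over 12 settings 0.0012 to 0.0525), and 5 to 8 members were lower with 1 array left out.

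Ribosomal protein genes gave 9 lower and 0 higher of 29 (7 and 0 adjusted over the list alone, camera adjusted p = 0.0132, adjusted p = 0.366 with an estimated correlation). Their median of -0.07 as deposited turned to 0.01 after cyclic loess, where the call was lost (camera adjusted p = 0.477, range over 12 settings 0.000445 to 0.477). The number lower was 6 after cyclic loess, 21 after centring and 29 with spike-in scaling. Rpl19 (-0.66, SE 0.045) and Rpl14 (-0.62, SE 0.0647) led, and both belong to genes with many processed pseudogenes. With 1 array left out 5 or 6 were lower. Glycolysis and hypoxia genes gave 7 higher and 5 lower of 23 (9 and 6 adjusted over the list alone, camera adjusted p = 0.323). The hypoxia-inducible genes Ndrg1 (1.40, SE 0.0488) and Bnip3 (1.01, SE 0.0461) rose, and Pfkp (-0.79, SE 0.0453) and Pdk1 (-0.74, SE 0.0616) fell, and Ndrg1 was 0.85 with the mean of probe sets. Leaving out 1 array gave 4 to 6 higher and 3 lower, centring 5 and 8, and spike-in scaling 3 and 16. Mitochondrial respiratory chain genes differed little on the deposited values, with 2 higher and 5 lower of 34 (0 and 2 adjusted over the list alone, median 0.04, camera adjusted p = 0.859) and 0 higher and 0 or 1 lower with 1 array left out. None was higher and 14 were lower after centring, and 34 of 34 were lower with spike-in scaling (median -0.50).

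**Figure D2:**
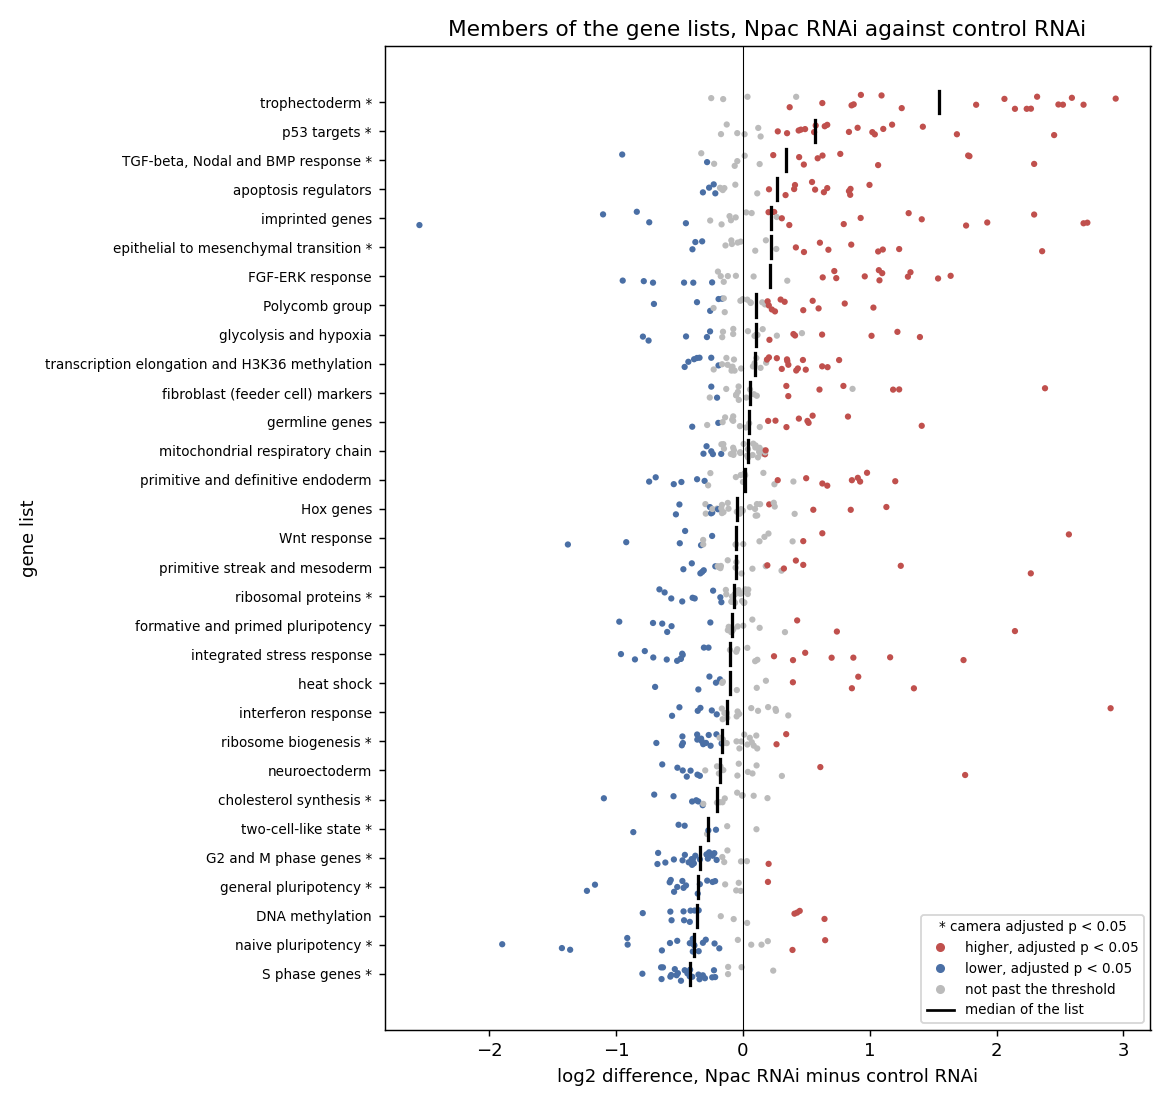
Log2 differences (Npac RNAi minus control RNAi, horizontal axis) of the measured members of the 31 gene lists (vertical axis), with a point per gene coloured by its limma call, a bar at the list median and a star for lists past the camera test. Stars are for the preset correlation, and 0 lists passed with an estimated one. The trophectoderm median lay at 1.55 and the p53 median at 0.57 (0.03 with spike-in scaling), and the medians of S phase and naive pluripotency genes at -0.42 and -0.39. The starred medians of TGF-beta response and epithelial to mesenchymal transition fell below 0 with spike-in scaling and that of ribosomal proteins rose above 0 after cyclic loess.

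By camera with the preset correlation 12 of the 31 lists passed, 4 higher and 8 lower, and with an estimated correlation 0 did (smallest adjusted p = 0.366). The estimate was -0.00414 for trophectoderm and -0.00666 for G2 and M phase genes, below the preset 0.01. For these lists a larger correlation was therefore not the reason for the loss. Other lists, such as the p53 targets (0.102), had estimates above the preset value. Fry, which tests a list's genes without comparing them with other genes, called 25 lists as moving on balance 1 way and 31 as changing in either direction. The median, mean and camera direction differed in sign for primitive streak and mesoderm, interferon response, heat shock, Hox genes and the mitochondrial respiratory chain.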

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

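All of the tests in this part were chosen after the results were seen. The following signals lay outside the gene comparison, and each differed from the control RNAi arrays. The 24 poly-A spike-in probe sets read higher on the Npac RNAi arrays by a mean log2 difference of 0.54 (SD over probe sets 0.135, 24 of 24 higher). As several probe sets read each of the transcripts dap, lys, phe and thr, they are not independent. The replicates differed by -0.0947 in control RNAi and by 0.0917 in Npac RNAi. The probe set for the B1 repeat, a short interspersed element of the mouse genome, read 0.86 higher in Npac RNAi (2 of 2 arrays above both control arrays), whereas those for the B2 repeat read -0.55 and -0.04. Of 9160 probe sets with no gene named in the annotation used here, 1766 changed (19.3%), 583 higher and 1183 lower. Of 932 probe sets naming several genes, 279 changed (29.9%), 99 higher and 180 lower. Among those naming 1 gene 30.5% changed, so neither class changed more often. Probe sets with no gene or several genes were not assigned to genes.

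The rise of the spike-ins was weighed first. Spike-ins are added before labelling, so brighter hybridization or scanning would raise the hybridization controls, added later, as much. Those rose by 0.12, in 18 of 18 probe sets, which lies below 0.54 by more than 2 SD of the spike-in probe sets. However, RMA would remove a brightening shared by a whole array. The hybridization controls were also brighter (array means 11.69 to 11.84) than the spike-ins (8.61 to 9.24). The comparison therefore cannot decide on brighter hybridization or scanning. Degraded RNA would raise the 3' minus 5' signal, and the larger change, that of Gapdh, was 0.0834 (0.0237 for Actb). A lower messenger RNA content per amount of total RNA, or a different amount of spike-in added, may each give the rise. Less messenger RNA per total RNA would raise the 18S ribosomal RNA signal with the spike-ins, but it was lower in 3 of 3 probe sets (-0.43, from -0.55 to -0.31), opposite to that prediction. This RNA lacks a poly-A tail, so its signal also depends on how it was primed, and the amount of spike-in added is not given in the sources used here. The explanations cannot be told apart, with the 18S values counting against less messenger RNA per total RNA.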

How the results depend on the processing

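Among the alternatives, scaling on the poly-A spike-ins, the crossed replicate block, the list tests after cyclic loess and spike-in scaling, and all tests of genes named after their values were seen, were chosen after the results were seen. Glyr1 kept its direction and its call in all 20 settings (-1.63 to -1.08, adjusted p 3.04e-08 to 0.0236). Of the values for named genes under alternatives, including those named after their values were seen, 2696 kept direction and side of the threshold, 322 lost the call, 13 gained it and 27 reversed. For gene lists these numbers were 347, 21, 48 and 16.

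Without moderation 2551 genes changed (1557 higher, 994 lower, 1010 by at least 1.5-fold). At an adjusted p under 0.01 it was 3129 (2115 and 1014), against a minimum of 1.2-fold (treat) 2108 (1579 and 529), and with a replicate block 4375 (1665 lower). A 2-fold minimum left 578. Over all probe sets, more features being tested, 12705 changed (6378 and 6327, 3511 by 1.5-fold). Centring gave 7175 lower, and spike-in scaling 15801 changed (906 and 14895, 9391 by 1.5-fold), which follows from their shifts. The crossed block gave 7033. With 1 array left out, fewer samples gave 3088 to 4731 changed, 2100 to 2761 higher and 988 to 1970 lower. Camera with an estimated correlation called 0 lists (the range otherwise was 11 to 16), fry 25 and fry in either direction 31.

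With spike-in scaling these genes reversed, as a shift of -0.54 implies: Zfp281 -0.34, Tbx3 -0.15, Cdc25b -0.34, Utp20 -0.20, Utp4 -0.28, Mbd1 -0.092, Sycp1 -0.022, Wnt3 -0.064, Ndufs1 -0.37, Ndufs7 -0.36, Epcam -0.059, Snai1 -0.12, Snhg11 -0.26, Col1a2 -0.43, Elf5 -0.12 and Esx1 -0.50. Genes uncalled on the deposited values also turned, the cause not tested: Col1a1 (quantile 0.039, cyclic loess 0.062, mean of probe sets 0.019, largest interquartile range 0.093, -0.11 to 0.00022 with 1 array left out), Col1a2 (centring -0.031), Elf5 (largest interquartile range -0.41, called lower there) and Esx1 (quantile and centring -0.10, -0.10 to 0.17 with 1 array left out). The test direction of these lists, uncalled by camera, turned, with the median given and the cause not tested: Hox genes (quantile -0.0078, cyclic loess 0.050, mean of probe sets -0.015), mitochondrial respiratory chain (centring -0.10, genes at or above the median level 0.036, mean of probe sets -0.041, 0.019 to 0.035 with 1 array left out, turning without Npac array 2, spike-in scaling -0.50, fry 0.036), heat shock (genes at or above the median level -0.10), glycolysis (same filter, 0.10), mesoderm (-0.15 to -0.032 with 1 array left out, turning without control array 1, -0.087), integrated stress response (spike-in scaling -0.64), Wnt response (spike-in scaling -0.60, fry -0.056) and interferon response (fry -0.13). For the other changes of counts the cause was not tested. The number of arrays limits the precision.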

Other observations

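All of the tests in this part were chosen after the results were seen.

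The families in this paragraph were picked after some of their members had been seen, so their tests do not exclude chance. Host genes of small nucleolar RNAs, which guide the modification of ribosomal RNA, were mostly lower. Of 14 Snhg genes 10 fell and 1 rose (median log2 difference -0.47, and -1.01 with 14 lower with spike-in scaling; camera adjusted p = 0.000244 over 4 families, p = 0.0666 with an estimated correlation). Snhg3 (-1.52, SE 0.077), Snhg6 (-0.95, SE 0.057), Snhg4 (-0.69, SE 0.0502) and Snhg8 (-0.62, SE 0.0556) led, and Snhg11 rose (0.28, SE 0.0768), but was -0.26 with spike-in scaling and lost its call without control array 2 and without either Npac array (adjusted p up to 0.158, highest over 20 settings 1). Any 1 array left out, 7 to 9 were lower and 0 or 1 higher. Guanylate-binding protein genes, known as interferon targets, rose, with 4 higher and 0 lower of 6 (median 0.87, and 0.33 with 3 higher and 2 lower with spike-in scaling; camera adjusted p = 0.00134, p = 0.0734 with an estimated correlation), namely Gbp2 (2.60, SE 0.0506), Gbp2b (2.42, SE 0.138), Gbp3 (0.95, SE 0.0519) and Gbp7 (0.79, SE 0.0759), the last without a call under spike-in scaling (0.25) or without moderation. These genes were dim too, with a family median level of 5.34, below the 25th percentile of all genes (5.51), so the sizes of their changes are uncertain. The placental prolactin genes did not rise, with 0 higher and 2 lower of 18 (Prl5a1 -0.34 and Prl7b1 -0.39; median -0.13, camera adjusted p = 0.0968), nor did the pregnancy-specific glycoproteins, with 0 higher and 1 lower of 7 (Psg21 -0.26; median -0.14, camera adjusted p = 0.221). The prolactin genes were dimmer, with a median level of 3.79. The calls on Prl5a1, Prl7b1 and Psg21 were weak, being lost in most fits with 1 array left out. They were also lost without moderation, as was that on Snhg11. After centring 7 prolactin genes and 2 pregnancy-specific glycoproteins were lower, and with spike-in scaling 18 of 18 and 7 of 7 (medians -0.67 and -0.68). Both scalings shift every difference by a constant (-0.14 and -0.54). These counts thus follow from the shifts and do not show a fall of such dim genes. Without Npac array 1 the prolactin family passed camera as lower (adjusted p = 0.0328, against 0.0761 to 0.892 under the other scalings and without each other array).

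The rise of trophectoderm markers was weighed against technical explanations. The scaling on spike-ins, the one that lowers the Npac RNAi arrays most, takes 0.54 from every difference and so leaves the median at 1.01 by arithmetic. The bootstrap spread of 0.493 is over genes of the list, not over arrays. This argues only against an array shift of that size as the whole cause. A lower share of stem cells might raise the markers of all other cell types alike. Against that narrower case, the trophectoderm median of 22 genes exceeded that of 118 markers from 6 other lists (-0.03) by 1.58. This is more than the SD of either set (1.02 and 0.56), a bound set after these values were known, and the other lists had medians from -0.28 to 0.06. Of the 118 markers 55 lay at or above the median level of all genes, so some are expressed by stem cells too, and the others had a median of -0.05. A lower share of stem cells with a rise of the trophectoderm lineage alone cannot be excluded in this way. Fibroblast feeder cells would bring their abundant transcripts, and 6 of these, dim in control RNAi (levels 3.81 to 6.79), had a median difference of -0.054, from -0.26 to 0.11, although Tagln, Acta2 and Col5a1 of the fibroblast list rose. No batch is given in the labels, and whether the groups were cultured or labelled together was not tested. A change of some or all cells toward trophectoderm after Npac depletion, with Pou5f1 lower, may explain the pattern. It is a hypothesis drawn from the same data and was not itself tested.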
